A study of Mus musculus with 8 samples.

How the data were processed

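RNA from progenitor cells sorted out of mouse bone marrow was measured on 8 Illumina MouseRef-8 v2.0 bead arrays. The cells were all-lymphoid progenitors (ALP) or common myeloid progenitors (CMP) from C57BL/6 mice, wild type or knockout for IRF-8, with 2 arrays in each of the 4 groups. Biotin-labelled RNA was amplified with a Nugen pico kit. Genotype was taken from the labels of each sample; the description of the design mentions wild-type mice alone. The labels do not say whether replicates were separate animals, so p-values measure only the spread between samples. Slide, scanner software and sort purity are not given in the sources used here.

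The deposited scanner table holds a linear signal intensity for each probe and array, with no normalization apparent in its values. Beside it the deposited table gives a detection p-value for each probe and array; 1 of its 8 columns carries no replicate number and was assigned to the array left over. The deposited gene table holds log2 values that the authors had quantile normalized and summarized over the probes of a gene by median polish, as worked out from the values themselves. The values were matched by rank within each array, which cannot show whether the background was adjusted. The scanner table has no gene names. Probes were therefore named by matching their values over the 8 arrays with those of the gene table within 0.0003 on the log2 scale, which linked 17686 of 18132 genes (97.5%) and 21812 of 25697 probes; 446 genes stayed unlinked. Of 2000 genes tried with their values in shuffled order, 0 were linked to a single probe. Of 300 genes of 3 probes tried in that way, 1 gave a spurious recurring difference. The search for means of 2 probes, which linked 2946 genes, was not tried on shuffled values, so its rate of false links is unknown. For 1148 genes of 3 or more probes, some probes alone were found. Names were brought to current symbols for 2660 genes, and 1167 names that had no unique current symbol were kept.

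Signals were background corrected from the detection p-values with the neqc method (offset 16), quantile normalized and taken to log2 with limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.05 on at least 2 arrays were kept (14280 probes), and each gene was represented by its probe with the highest mean. This left 12234 features, 9652 named genes and 2582 unnamed probes. A single linear model of the 4 group means was fitted with limma (4 residual and 3.58 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The comparisons were knockout against wild type in ALP and in CMP, the difference between these effects, and wild-type ALP against wild-type CMP. A fold is given as "at least" where the lower group was not detected on any of its arrays, taken against the mean over those arrays of the lowest detected signal. Other scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

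There were 22 gene lists, fixed before the data were examined: neutrophil primary granule, neutrophil late granule and receptor, MHC class II presentation, conventional dendritic cell, plasmacytoid dendritic cell, monocyte and macrophage, phagocyte NADPH oxidase, megakaryocyte and erythroid, B lymphoid, T lymphoid, NK and innate lymphoid, stem cell and multipotent progenitor, mast cell with basophil and eosinophil, interferon response, MHC class I presentation, cell cycle, hematopoietic transcription factor, sort marker, plasma cell and mature B cell, immediate early and heat shock, ribosomal protein, and stromal and endothelial. They were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and with fry. The comparisons, the settings, the alternatives and the rule for naming genes were fixed at the same time. By that rule Irf8 came first, then up to 12 genes each way past the threshold in each knockout comparison with both knockout arrays beyond both wild-type arrays, up to 8 each way in the other comparisons, up to 4 members with the largest change of each list described, and the 10 genes with the smallest p where fewer than 5 passed. Other genes are named as members of a list that passed over the list alone, or as chosen after their values were seen. Which lists have their members and medians described was narrowed after the data were examined and after it was seen which of them changed sign between settings; counts over all 22 lists are given with the dependence on processing.

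The alternatives were no background correction, an offset of 50, median scaling, cyclic loess, the authors' values, no filter, a stricter detection filter, every probe by itself, the 4 arrays of a comparison alone, an intensity trend with robust fitting, array weights, stricter and looser thresholds, a block for the replicate number and leaving out each array. A block for the slide was not run, since no slide is given. The method was tested on simulated data with 12234 genes on 8 arrays: of 50 genes for each size it recovered 2 at a log2 change of 1, 25 at 2, 41 at 3 and 45 at 4, and 5 of the 118 genes called had no change. Each simulated gene had the same spread in all 4 groups, with no outlying array and no correlation between genes. The real wild-type ALP arrays varied more than the others, so these rates may not hold for ALP. The number of arrays limits the precision of every value.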

Results

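Transcript levels were measured in ALP and CMP from wild-type mice and from mice lacking IRF-8, a transcription factor of the interferon regulatory factor family known for its part in the development of monocytes, dendritic cells and B cells. Each of the 4 groups had 2 arrays, which limits the precision of every estimate. Between 11122 and 12749 probes were detected per array, which is 43.3% to 49.6% of all probes. Wild-type ALP array 2 stood apart from the rest, with the fewest probes detected and a mean correlation across genes of 0.831 with the other arrays, and the wild-type ALP arrays correlated with each other at 0.844, against 0.939 to 0.95 within the other groups. The title of the series names neutrophil production and dendritic cell commitment in myeloid and lymphoid progenitors as its subject.

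The Irf8 probe had log2 levels of 10.97 and 10.89 in wild-type ALP, 11.40 and 11.17 in knockout ALP, 11.06 and 10.96 in wild-type CMP, and 10.83 and 10.81 in knockout CMP. Its knockout change was 0.36 (SE 0.26, adjusted p = 0.606) in ALP and -0.19 (SE 0.26, adjusted p = 0.976) in CMP. Where the probe lies relative to the disrupted part of the gene is unknown here, so it checks neither the genotype nor the labels.

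In knockout ALP, Ctsg, which encodes the granule protease cathepsin G, rose by 2.88 on the log2 scale (SE 0.28, adjusted p = 0.0247), with both knockout arrays above both wild-type arrays. Hk3, a hexokinase of myeloid cells, rose by 4.65 (SE 0.35, adjusted p = 0.0188), and Ccl9, a chemokine, rose by 3.33 (SE 0.36, adjusted p = 0.0387). Hk3 was detected on 1 of the 2 wild-type ALP arrays, so the size of its rise is uncertain. Ly86, which encodes MD-1, the partner of the receptor RP105 in lymphoid and antigen-presenting cells, fell at least 7.82-fold (log2 -3.55, SE 0.31, adjusted p = 0.0247), from 8.66 and 8.12 to 4.72 and 4.94.

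In all, 16 features passed in ALP, 12 higher and 4 lower in the knockout, of which 11 and 2 were named genes. The other named genes that rose were Rab44 (4.87), Aatk (4.28), Dram1 (4.04, at least 9.86-fold), Diras2 (3.16, at least 5.89-fold), Rhbdd3 (2.75, at least 3.45-fold), Hpse (2.69), which encodes heparanase, Mapk11 (2.55, at least 4.58-fold) and Stk11ip (2.26, at least 3.74-fold). A second probe gave 1.98 for Rab44 and 1.14 for Mapk11. Rab44 and Aatk were each detected on 1 wild-type ALP array. Hrh1, a histamine receptor, was the other named gene that fell (log2 -2.80, SE 0.35, adjusted p = 0.0466, at least 5.41-fold). In every one of these genes both knockout arrays lay beyond both wild-type arrays, as they did for 42.2% of all features. The model used 1 shared spread, while the median SD of 2 arrays was 0.375 in wild-type ALP and 0.214 to 0.26 in the other groups. An unadjusted p under 0.05 was reached by 1191 features with array weights and 1182 with the 4 arrays of ALP alone. With 1 spread for all 4 groups there were 1636 features, 927 higher and 709 lower, where chance gives 612. A fit without wild-type ALP array 1 leaves the outlying array 2 as the only wild-type ALP array. The deviations of that array then enter every change in ALP without adding to the spread, which can raise the number of features that pass. The count was 990 without wild-type ALP array 1 and 24 without wild-type ALP array 2, and it was 0 by limma without any single one of the other 6 arrays, with 987 to 1537 features at an unadjusted p under 0.05.

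The neutrophil primary granule list was higher in knockout ALP, with a median of 0.461 and 11 of 15 members above 0 (adjusted p = 0.0187 by fry and 0.00313 by camera). It holds proteases stored in the granules that form first along with other genes, so it does not measure granule contents alone. The call was not made with an estimated correlation (adjusted p = 0.365 with an estimated correlation), nor without wild-type ALP array 1 (median 0.615, adjusted p = 0.152); without wild-type ALP array 2 the median was 0.706 (adjusted p = 0.00309). Over all genes 1 member passed, Ctsg; adjusted over the list alone 5 did, Ctsg, Prtn3 (2.95, SE 0.42, adjusted p over all genes 0.0584), ELA2, the table's older name for neutrophil elastase (2.13, SE 0.58, 0.209), Mpo, myeloperoxidase (1.39, SE 0.28, 0.126), and Serpinb1a. In wild-type ALP array 1 and array 2 the Prtn3 level was 7.22 and 6.09, against 9.29 and 9.91 in the knockout. Late granule and receptor genes gave no call (adjusted p = 0.873): their median was 0.138 while their mean was -0.1 and the test pointed down, and Fpr2 had a value of -1.41 (at least 1.94-fold lower) and Mmp8, detected on 1 ALP array, a value of 0.4. That median was -0.039 without wild-type ALP array 1.

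Immediate early and heat shock genes, which respond within minutes to stimulation or handling, were lower in knockout ALP (median -0.412, 17 of 21 members below 0, adjusted p = 0.00313 by camera, adjusted p = 0.588 with an estimated correlation, and 0.427 without wild-type ALP array 1). The median was -0.175 without wild-type ALP array 1 and -0.679 without wild-type ALP array 2. Over all genes 0 of them passed in limma; adjusted over the list alone 4 did, Egr1 (-1.75), Btg2 (-1.21), Zfp36 and Ier2. The stem cell and multipotent progenitor list was lower too (median -0.363, adjusted p = 0.0474, adjusted p = 0.588 with an estimated correlation), with 0 of 24 members past the threshold over all genes and 2, Egr1 and Mycn (-1.28), adjusted over the list alone. Its adjusted p was 0.427 (median -0.23) without wild-type ALP array 1, 0.0596 without wild-type ALP array 2 and 0.103 without knockout ALP array 2. The interferon response list was the remaining one called (median -0.311, 25 of 37 members below 0, adjusted p = 0.0474, adjusted p = 0.704 with an estimated correlation). Adjusted over the list alone 2 of its members passed, Ifi27 (-2.23) and Gbp3 (-1.50), and 0 did over all genes. Its adjusted p was 0.152 (median -0.54) without wild-type ALP array 1, 0.329 without wild-type ALP array 2 and 0.201 without knockout ALP array 2.

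The other lists gave no call in ALP by camera. Among monocyte and macrophage genes (adjusted p = 0.122, and 0.0386 without knockout ALP array 1) Ccl9 rose and Ly86 fell, and F13a1, coagulation factor XIII A, had a value of 3.23 (SE 0.42, adjusted p = 0.0523). MHC class II genes went both ways (adjusted p = 0.639): H2-Aa had a value of -2.14 (adjusted p = 0.116, at least 3.14-fold lower) and Cd74, the invariant chain, -1.39 (0.269), while H2-Ab1 had 1.99 (0.12) and H2-Oa 1.47 (0.208). Adjusted over the list alone, 2 of these were higher, H2-Ab1 and H2-Oa, and 1 lower, H2-Aa. B lymphoid genes had a median of 0.113 (adjusted p = 0.767, median -0.004 without wild-type ALP array 1), with Vpreb1, a surrogate light chain, at 2.96 (SE 0.40, adjusted p = 0.0544, at least 6.67-fold) as the 1 member past the threshold over the list alone. Plasmacytoid dendritic cell genes, called lower by fry (adjusted p = 0.0455) and not by camera (adjusted p = 0.182), had a median of -0.043, with Rnase6 at -3.21 (SE 0.44, adjusted p = 0.0544) and Pld4 at -1.89. Conventional dendritic cell genes had an adjusted p of 0.866. The adjusted p of the remaining lists was 0.122 for the phagocyte NADPH oxidase, 0.153 for NK and innate lymphoid, 0.316 for T lymphoid, 0.316 for stromal and endothelial, 0.444 for cell cycle, and 0.639 for each of MHC class I, ribosomal protein, plasma cell, and mast cell with basophil genes. It was 0.769 for megakaryocyte and erythroid genes and 0.873 for hematopoietic transcription factors and for sort markers.

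**Figure D1:**
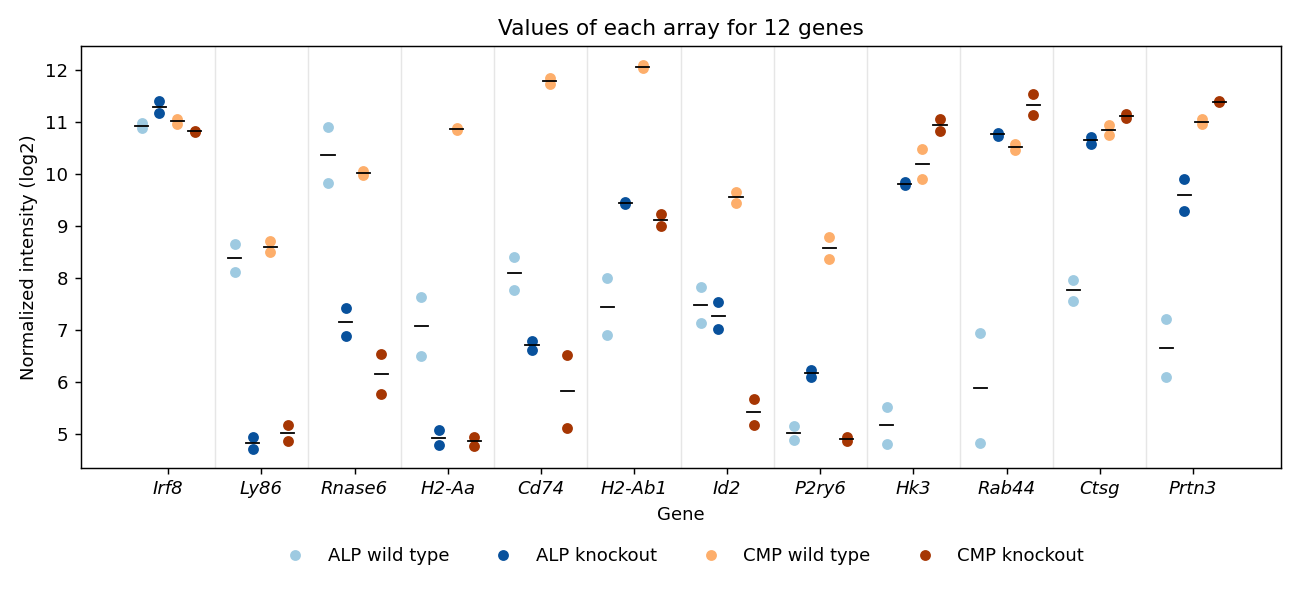
Normalized log2 intensity of 12 genes in each of the 8 arrays. Points are arrays, coloured by cell type and genotype, and black lines are the means of 2 arrays; Ly86 lies between 8.12 and 8.71 in the wild-type arrays and between 4.72 and 5.17 in the knockout arrays.

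In knockout CMP, genes of antigen presentation by MHC class II were lower. H2-Aa, which encodes a class II alpha chain, fell at least 41.9-fold (log2 -6.01, SE 0.40, adjusted p = 0.00694), from 10.89 and 10.85 to 4.77 and 4.95. Cd74 fell by 5.96 (SE 0.47, adjusted p = 0.00694). H2-Eb1 (log2 -3.71, SE 0.42, adjusted p = 0.0356), H2-Ab1 (log2 -2.95, SE 0.38, adjusted p = 0.0493) and Ifi30, the thiol reductase of antigen processing (log2 -2.27, SE 0.29, adjusted p = 0.0493), fell too. Id2, a regulator that dendritic and innate lymphoid cells need, fell by 4.13 (SE 0.36, adjusted p = 0.0092), and Ly86 fell at least 8.71-fold (log2 -3.58, SE 0.31, adjusted p = 0.0092). A second probe gave -5.30 for Cd74, -2.80 for H2-Ab1 and -3.03 for Id2. Cd74, H2-Eb1 and Id2 were each detected on 1 of the 2 knockout CMP arrays, so the size of their falls is uncertain.

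Of all features 18 passed in CMP, 2 higher and 16 lower in the knockout, of which 1 and 14 were named genes. Trem3, a myeloid receptor, was the named gene that rose (2.93, SE 0.35, adjusted p = 0.0405). The others that fell were Rnase6 (-3.88), Ctsh (-3.68, at least 8.28-fold), a lysosomal protease, P2ry6 (-3.67, at least 8.54-fold), a nucleotide receptor, Lgals3 (-2.79, at least 4.36-fold), galectin 3, Aif1 (-2.47, at least 4.45-fold), Plbd1 (-2.43) and Marchf1 (-2.09, at least 3.01-fold), a ubiquitin ligase that acts on class II molecules and was chosen for naming after its values were seen. In each of these genes both knockout arrays lay beyond both wild-type arrays, as they did for 38.8% of all features. Plbd1 was detected on 1 knockout CMP array and Trem3 on 1 wild-type CMP array, so the sizes of their changes are uncertain. An unadjusted p under 0.05 was reached by 977 features with array weights and 964 with the 4 arrays of CMP alone. With 1 spread for all 4 groups, to which the more variable wild-type ALP arrays contribute, there were 672 features, where chance gives 612. Without a single array of CMP the count was 0 or 1 by limma, 0 without either wild-type array or knockout array 2 and 1 without knockout array 1, with 414 to 883 features at an unadjusted p under 0.05. It was 6 without either knockout ALP array and 24 without either wild-type ALP array.

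All 11 MHC class II genes tested had values below 0, with a median of -2.187 (adjusted p = 8.52e-18 by camera, and adjusted p = 0.0158 with an estimated correlation). Over all genes 5 of them passed, and adjusted over the list alone 8 did. The median lay between -1.742 and -2.265 without each array in turn, with the call kept each time. Knockout CMP array 2 had a median signal of 233.3, against 163.8 to 180.5 in the other arrays, and without it the median was -2.103 (adjusted p = 3.35e-18). The conventional dendritic cell list was lower as well (median -0.506, 13 of 16 members below 0, adjusted p = 7.02e-07, adjusted p = 0.0507 with an estimated correlation). Id2 passed over all genes, and adjusted over the list alone 6 did, among them Batf3 (log2 -1.92, SE 0.26, adjusted p over all genes 0.0554, at least 2.41-fold) and Clec9a (-1.10, 0.426, at least 1.4-fold), genes of the dendritic cells that cross-present.

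**Figure D2:**
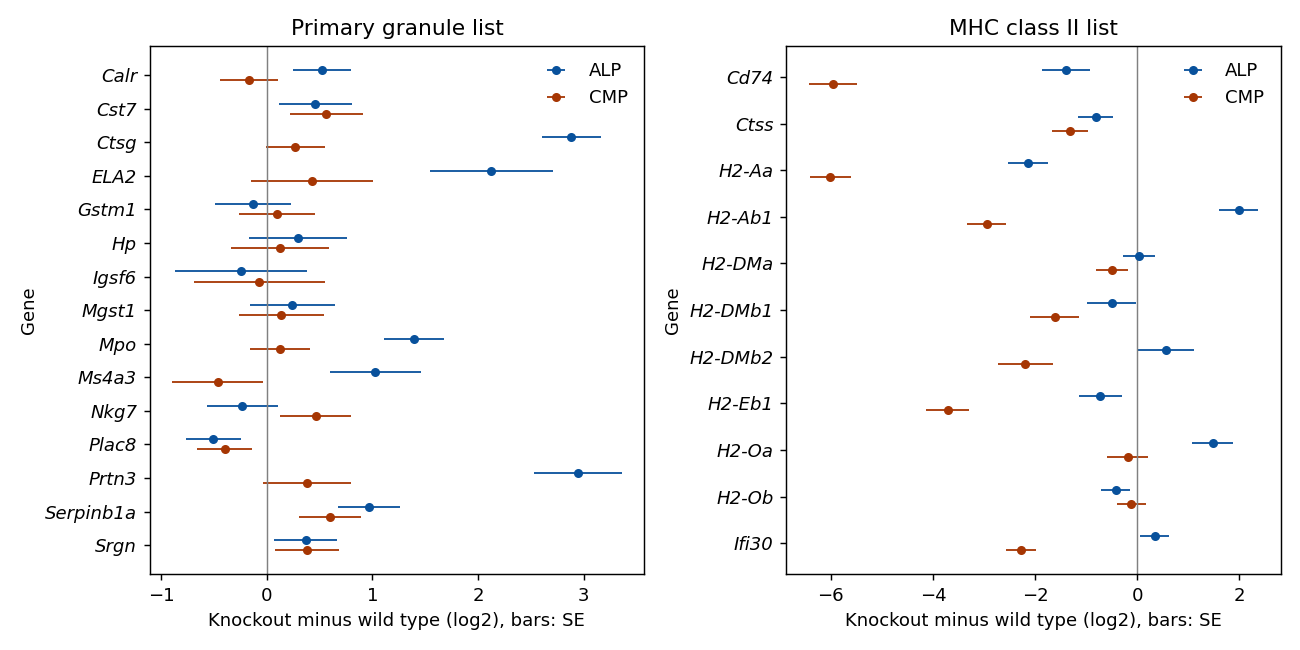
Knockout minus wild-type log2 change of each tested gene of the primary granule list (left) and the MHC class II list (right) in ALP and CMP. Points are estimates from 2 arrays against 2 and bars are SE; all 11 class II values in CMP lie below 0, while those in ALP lie on both sides.

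Cell cycle genes were lower in knockout CMP (median -0.399, 35 of 38 members below 0, adjusted p = 5.98e-07, adjusted p = 0.145 with an estimated correlation). Over all genes 0 passed in limma, and adjusted over the list alone 1 did, Plk1, a mitotic kinase (-1.89, SE 0.37). Without wild-type CMP array 2 the median was -0.253 (adjusted p = 0.000301). Monocyte and macrophage genes were called lower (adjusted p = 0.00284, adjusted p = 0.341 with an estimated correlation) with a median of -0.048. Of its 21 members 2 fell over all genes, Ly86 and Lgals3, and 4 adjusted over the list alone, with Klf4 (-2.31, at least 3.54-fold, and -1.47 at a second probe) and Ms4a6c (-1.89) besides. Without knockout CMP array 1 the median was 0.003 and the adjusted p 0.0985, and the median was -0.358 without knockout CMP array 2, -0.092 without wild-type CMP array 1 and -0.155 without wild-type CMP array 2. Immediate early and heat shock genes had a median of -0.41 (adjusted p = 0.0314, adjusted p = 0.714 with an estimated correlation), with 0 of 21 members past the threshold over all genes or adjusted over the list alone. Their adjusted p was 0.699 (median -0.064) without wild-type CMP array 1, 0.162 without knockout CMP array 1 and 0.053 (median -0.222) without knockout CMP array 2.

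The primary granule genes had a median of 0.14 in knockout CMP (adjusted p = 0.336, median -0.031 with median scaling), and the late granule genes 0.106 (adjusted p = 0.736, median -0.042 without knockout CMP array 2), with Mmp8 at 1.69 (at least 2.02-fold). Plasmacytoid dendritic cell genes had an adjusted p of 0.578, B lymphoid genes 0.529 and interferon response genes 0.81. For the rest the adjusted p was 0.263 for T lymphoid, 0.336 for stem cell, 0.336 for ribosomal protein, 0.477 for NK and innate lymphoid, 0.578 for MHC class I, and 0.81 for each of megakaryocyte and erythroid, mast cell with basophil, NADPH oxidase, transcription factor, sort marker, plasma cell, and stromal and endothelial genes. Wild-type CMP array 2 carried transcripts of red cells and platelets that wild-type CMP array 1 did not: Mfsd2b stood at 9.10 against 5.42, Aqp1 at 8.58 against 5.26, Gp5 at 7.78 against 4.96 and Ermap at 7.39 against 4.88. The knockout values of these genes were -1.45 for Mfsd2b and -1.24 for Aqp1, and without wild-type CMP array 2 they were 0.388 and 0.417.

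Of the features that passed, 1 did so in both cell types, Ly86, lower in each, where independent lists would share 0.00523. At an unadjusted p under 0.05, 75 features were higher in both (23.5 by chance), 71 lower in both (21 by chance) and 41 went opposite ways (45.4 by chance). The changes in the cell types correlated across genes at r = 0.205 (Spearman 0.188), and genes are not independent replicates. Both comparisons used separate wild-type arrays.

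The knockout effect itself differed between the cell types for 1 gene, P2ry6, by at least 3.66 on the log2 scale (adjusted p = 0.0418), since it was not detected in wild-type ALP or knockout CMP: its values went from 4.89 and 5.15 to 6.09 and 6.24 in ALP and from 8.36 and 8.78 to 4.95 and 4.87 in CMP. The 9 genes with the next smallest p did not pass: H2-Ab1 (4.93, SE 0.54, adjusted p = 0.112), LOC641240, Ckb (at least 5.60), Hk3 (3.89), Id2 (3.93), Rap2a (at least 2.45) and Lgals3, with H2-Aa and Pcyox1l (at least 2.89) at an adjusted p of 0.144. Lgals3 was detected in wild-type CMP alone and H2-Aa in no knockout array, so the size of their difference is unknown. At an unadjusted p under 0.05 there were 868 features, where chance gives 612. Here too, a fit without wild-type ALP array 1 takes in the deviations of the outlying array 2. The count was 36 without wild-type ALP array 1, 7 without wild-type ALP array 2 and 0 by limma without any single other array. Of the 22 lists 8 were called by camera, and 1 of them, MHC class II (median difference 2.612, adjusted p = 2.19e-10), was called with an estimated correlation (adjusted p = 0.0446 with an estimated correlation). A class II gene near background in wild-type ALP, such as H2-Eb1, could not fall there as far as in CMP.

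In the wild type, Rag1, the recombinase of antigen receptor genes, was at least 11.5-fold higher in ALP (log2 3.95, SE 0.35, adjusted p = 0.00443), and Il7r, the receptor on which ALP were sorted, at least 8.92-fold higher (log2 3.68, SE 0.26, adjusted p = 0.00379). St6gal1 (4.57), Slc35d3 (4.55, at least 15.7-fold) and Cmah (4.29) were higher in ALP, as were Gm5111, Il18r1 and Emp1. Hk3 was lower in ALP (-5.02, SE 0.35, adjusted p = 0.00379), as were H2-Ab1 (-4.61), Prtn3 (-4.35), Ckb, Rab44, Dram1, Aatk and LOC641240. In all 177 features passed, 82 higher and 95 lower in ALP, 1838 had an unadjusted p under 0.05, and the arrays of the groups did not overlap for 43.7% of all features. As for the knockout effect in ALP, a fit without wild-type ALP array 1 takes in the deviations of the outlying array 2, which can raise the count. The count was 1227 without wild-type ALP array 1, 0 by limma without either wild-type CMP array (1272 without array 1 and 1081 without array 2 at an unadjusted p under 0.05), and 88 or 94 without a knockout array. Primary granule (median -1.436), monocyte and macrophage (-1.108) and class II genes (-1.147) were lower and T lymphoid (1.092) and B lymphoid genes (0.263) higher in ALP, with 12 lists called by camera. With an estimated correlation 0 lists were called, with an adjusted p = 0.0518 with an estimated correlation for granule, monocyte, class II and B lymphoid genes and 0.0609 for T lymphoid genes. By fry 12 lists were called. Without wild-type ALP array 1 the median was -1.776 for class II genes and 0.559 for B lymphoid genes. With all arrays the class II gene H2-Ob was higher in ALP (2.42, adjusted p = 0.0108).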

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

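The tests of explanations below were all chosen after the results they measure had been seen; the comparisons themselves were planned.

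The knockout effect differed between ALP and CMP for P2ry6 by at least 3.66 on the log2 scale; the fitted 4.811 is no measured size, since P2ry6 was not detected in wild-type ALP or knockout CMP. For lists, the median difference between the effects was 2.612 for MHC class II genes, 0.614 for conventional dendritic cell genes, 1.045 for monocyte and macrophage genes and 0.472 for cell cycle genes. It was 0.174 for primary granule genes, -0.624 for T lymphoid genes, -0.394 for stem cell genes and -0.219 for interferon response genes. Of the list members, Batf3, Clec9a, Lgals3 and Ms4a6c were detected on no ALP array and H2-Eb1 on 1 wild-type ALP array. A gene near background in wild-type ALP cannot fall there as far as in CMP, which limits the meaning of these medians. Leaving out single arrays moved these medians to between 0.072 (without knockout ALP array 1) and 0.64 (without wild-type ALP array 1) for primary granule genes, where it was also 0.55 without wild-type ALP array 2, 0.467 without knockout ALP array 2, 0.501 without wild-type CMP array 1 and 0.267 without knockout CMP array 2. T lymphoid genes had -0.277 without wild-type ALP array 1 and -0.386 without wild-type CMP array 2, and monocyte genes 0.588 without wild-type ALP array 2 and 0.668 without knockout ALP array 2. Interferon response genes had -0.122 without wild-type ALP array 2, -0.403 without wild-type ALP array 1, -0.425 without knockout ALP array 1, -0.483 without wild-type CMP array 2 and -0.708 without knockout CMP array 2. With an estimated correlation the adjusted p was 0.0446 for MHC class II, 0.145 for conventional dendritic cell, 0.169 for monocyte and cell cycle, 0.182 for primary granule, 0.272 for stem cell, 0.38 for T lymphoid and 0.661 for interferon response genes. Without wild-type ALP array 1 the adjusted p with the preset correlation was 0.176 for primary granule, 0.219 for stem cell, 0.306 for T lymphoid and 0.0764 for interferon response genes. Without wild-type CMP array 2 it was 0.0736 for primary granule and for T lymphoid genes, without knockout ALP array 2 it was 0.0935 for T lymphoid genes, and without knockout CMP array 1 it was 0.0937 for primary granule genes. For interferon response genes it was 0.235 without wild-type ALP array 2 or knockout ALP array 2, 0.275 without wild-type CMP array 1 and 0.562 without knockout CMP array 1.

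The primary granule list was called higher in knockout ALP by fry (adjusted p = 0.0187) and by camera with the preset correlation. It was not called by camera with an estimated correlation (adjusted p = 0.365). Among single genes, 11 named ones rose, Ctsg of that list among them. Without the outlying wild-type ALP array 2 the granule list kept a median of 0.706 (adjusted p = 0.00309), which argues against that array as the cause, though without wild-type ALP array 1 the adjusted p was 0.152. Cells of the CMP type within the knockout sort may account for part of it: 10 of 15 genes of the pattern need a share of 21.8% to 69.1% (median 49.6%), and at that median 7 lymphoid genes stood 0.42 above their diluted level (SE over genes 0.14), but over 2 ways of taking the share, with and without each ALP array, the gap was 0.29 to 0.78, over 2 SE in 9 of 10 (not without knockout ALP array 1, 0.29, SE 0.15), and it was 0.18 (SE 0.14) at 36.5%, the median share that 32 genes lower in wild-type ALP need, and -0.05 at the lowest share. The SE of each gap covers the spread over 7 genes and not the spread between arrays. The 10 settings share arrays and genes, so they are not separate pieces of evidence. The 66 genes higher in wild-type ALP had a median of -0.64 in knockout ALP, but both sets were picked on the arrays they are measured against, which can move them this way without any admixture (-0.45 and -0.11 for 78 genes picked on wild-type ALP array 1 and 196 picked on the outlying array 2, each measured against the other array). For genes lower in ALP picked in the same ways, the medians were 1.13 (53 genes) and 0.18 (192 genes). Of genes high in CMP, Mcpt8 reached a level that needs 35.1%, Hdc 8.77% and Gata2 2.74%, and 5 genes of the pattern lay above knockout CMP, Hpse, Diras2 and Rhbdd3 by 0.43 to 0.56 and Stk11ip and Mapk11 by 1.90 and 2.17 (SE 0.26 and 0.29), which argues against such cells as the source of the last 2, while for the 10 genes a changed mixture of cells and a change within each lymphoid progenitor cannot be told apart and the effect of the genotype stays open.

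MHC class II genes were lower in knockout CMP. The higher background of knockout CMP array 2 is argued against by the median of -2.103 without that array (adjusted p = 3.35e-18). Loss of a class II-rich kind of cell from the knockout sort and a lower level in each cell were not tested, and both stay open.

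Genes shifted the same way by genotype in both cell types were more frequent than chance gives. Passenger DNA around Irf8, carried over from the strain in which a knockout is made, is argued against as the source of the set: of the 100 tested genes nearest to Irf8 only 1 was shifted the same way, against 1.21 by chance (one-sided exact p = 0.705). An effect of the genotype, and a difference between the slides or days of the genotypes, stay open, since neither slide nor day is given in the sources used here. The test looked near Irf8 alone, so a difference of strain background elsewhere in the genome stays open too.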

How the results depend on the processing

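All alternatives were planned; the choice of which lists and genes to follow was made after seeing the data. Over all 22 lists and both knockout comparisons 50 of 922 medians changed sign, 1 of them of a called list, and 34 of 3587 values of genes under the naming rule did, 0 of them of a called gene. H2-Aa in CMP passed in 12 of 12 alternatives (-7.669 to -3.756) and in 4 of 8 fits without an array, Ly86 in CMP in 11 and 4, and Ly86, Hk3 and Ctsg in ALP in 10 and 2. P2ry6 passed for the difference between the effects in 7 of 11 alternatives and in 2 of 8 fits without an array (adjusted p 0.0191 to 0.471). Other named genes were less firm. In ALP, Hrh1 passed in 2 of 12 alternatives, Diras2 in 4, Mapk11 in 5, Rab44 in 6 and the rest in 7 to 9. In CMP, Plbd1 passed in 6. MHC class II genes were called lower in CMP in every alternative. For the changes below the cause was not tested, save that fewer arrays leave fewer degrees of freedom and that a change of filter changes the number of genes tested. Where an array is left out, the lone array of its group is assumed to vary like the others. Without wild-type ALP array 1 this assumption falls on the outlying array 2, whose deviations then enter the changes without adding to the spread. High counts from that fit are therefore not counts of knockout effects. The block for the slide was not run.

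The count in ALP (16) was 6 with cyclic loess, 6 with no filter, 30 with the stricter detection filter, 0 with the 4 arrays alone, 34 with trend and robust fitting, 6 with array weights and 50 at an adjusted p under 0.1. The count in CMP (18) was 8 with the authors' values and 28 with array weights. The count of differing effects (1) was 8 with no background correction, 2 with offset 50, 0 with median scaling, 0 with cyclic loess, 0 with no filter, 2 for every probe, 5 with trend and robust fitting and 2 with array weights. The count between the wild types (177) was 0 with the 4 arrays alone, 101 with array weights and 374 at an adjusted p under 0.1. The count in both cell types (1) was 2 with no background correction, offset 50, the stricter filter or trend and robust fitting (Ly86 and Rnase6), 0 with the 4 arrays alone and 3 at an adjusted p under 0.1 (Ctsh besides). With the replicate block the counts were 0 in ALP, 1 in CMP, 0 for differing effects, 57 between the wild types, 0 in both, and 2 lists in ALP. Deviations under the same replicate number correlated across genes at -0.097 to 0.0761. No pairing is seen in these values, but with 2 arrays per group they cannot exclude it. Beside the counts of 0 by limma, unadjusted p under 0.05 gave 1182 features in ALP and 1302 between the wild types with the 4 arrays alone, 1452 in ALP and 746 for differing effects with the block, and 911, 899 and 1411 for differing effects with median scaling, loess and no filter.

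The number of lists called in ALP (4) was 2 with median scaling, 2 with the 4 arrays alone, 2 with array weights, 0 with an estimated correlation and 2 with fry. In CMP (5) it was 3 with no filter, 1 with an estimated correlation and 4 with fry (MHC class II, conventional dendritic cell, monocyte and cell cycle genes). With fry 6 lists were called for the difference between the effects. The granule list in ALP, median 0.461, had an adjusted p of 0.365 with an estimated correlation. Median scaling moved the median of all genes by -0.144 in CMP and gave the granule list there -0.031. The authors' values gave the conventional dendritic cell list 0.14 in ALP and Ifitm1 0.097 in CMP. The stricter filter gave that list 0.036 in ALP, and B lymphoid genes -0.092 in ALP and 0.015 in CMP.

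Without each array in turn, the counts ranged from 0 to 990 in ALP, 0 to 24 in CMP, 0 to 36 for differing effects, 0 to 1227 between the wild types and 0 to 5 in both. Lists called ranged from 0 to 5 in ALP and 3 to 7 in CMP. The granule list in ALP ranged from 0.461 to 0.706. Late granule genes ranged from -0.039 to 0.259 in ALP and -0.042 to 0.114 in CMP, B lymphoid genes from -0.004 to 0.181 in ALP, and in CMP plasmacytoid dendritic cell genes from -0.175 to 0.016, monocyte genes from -0.358 to 0.003 and interferon response genes from -0.308 to 0.099. In ALP Ceacam1 ranged from -1.854 to 0.169 and Lair1 from -1.329 to 0.263. In CMP Lrg1 ranged from -0.044 to 0.623, Mfsd2b from -3.293 to 0.388, Aqp1 from -2.904 to 0.417, Gp5 from -2.418 to 0.395 and Ermap from -2.212 to 0.299. Signal close to background limits the genes given as at least a fold, and every log2 value of a gene not detected in 1 of the groups compared.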

Other observations

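The test values in this part were computed by the planned comparisons, while Diras2, Rhbdd3, Trem3 in ALP, Bcl6, the H2-Ab1 comparison and the unlinked genes were chosen after their values were seen.

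Hematopoietic transcription factors gave no list call in either cell type by camera, with 0 of 46 past the threshold over all genes in ALP by limma and 1, Id2, in CMP. Adjusted over the list alone, 5 passed in ALP: Bcl11a (-2.16, SE 0.38), a factor of B cell and plasmacytoid dendritic cell development, Egr1 and Mycn were lower, and Spi1 (1.53, SE 0.36), which encodes PU.1, and Foxo1 (1.44, SE 0.36) were higher. In CMP 4 passed in that way, all lower: Id2, Batf3, Bach2 (-2.63, SE 0.46) and Bcl6 (-1.50, SE 0.33). Over all genes the adjusted p was 0.111 for Bcl11a, 0.164 for Spi1, 0.187 for Foxo1, 0.173 for Bach2 and 0.379 for Bcl6, and in each of these both knockout arrays lay beyond both wild-type arrays.

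Besides Ly86, several genes had values on the same side in both cell types. Diras2 had 3.16 (at least 5.89-fold) in ALP, where it passed, and 2.53 in CMP (adjusted p = 0.108). Rhbdd3 had 2.75 (at least 3.45-fold) in ALP, where it passed, and 1.79 in CMP (0.101). Trem3 had 1.63 in ALP (0.139) and 2.93 in CMP, where it passed. Diras2 and Rhbdd3 were detected in neither wild-type group and Trem3 not in wild-type ALP, so these sizes are limited by background and cannot be compared between the cell types. Rnase6 had -3.21 in ALP (0.0544) and -3.88 in CMP, where it passed, and Pld4, a nuclease of plasmacytoid dendritic and B cells, had -1.89 and -2.04 and passed in neither. H2-Ab1 stood at a mean of 9.44 in knockout ALP and 9.11 in knockout CMP, above its wild-type ALP arrays (6.91 and 7.99) and below its wild-type CMP arrays (12.09 and 12.03), while H2-Aa was between 4.77 and 5.08 in all 4 knockout arrays.

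Of the 446 genes of the authors' table that no probe was linked to, 3 passed between wild-type ALP and CMP in the authors' values: Arpp21 (2.47, SE 0.32) and Cd6 (2.44, SE 0.29) were higher in ALP and Rassf4 (-3.47, SE 0.49) lower. In the knockout comparisons and their difference 0 of these genes passed in limma.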
